A study of Homo sapiens with 44 samples.

How the data were processed

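The series profiled chromatin of HT1080, a human fibrosarcoma cell line, by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels' protocols, parental cells (WT) were compared with transfected clones that stably carried EGFP-tagged DDIT3, FUS-DDIT3 or EWS-FLI1 and were grown with G418. The labels list 44 samples. Of these, 30 have a peak list of their own and 14 are inputs, for which no file was analysed here. The 30 lists form 15 groups with 2 replicates each: the DDIT3 antibody in the DDIT3, FUS-DDIT3 and WT lines, and CTCF, H3K27ac and H3K27me3 in all 4 lines. A further list of the DDIT3 antibody in the DDIT3 line is named as pooled in the series. Groups and replicate numbers came from the titles and characteristics of the samples. Nothing in the labels says whether replicates came from separate cultures, so p-values of permutation tests over lists measure the spread between these samples, which may be technical. Fisher's exact tests run over genes or regions and leave the spread between samples out.

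Per the submitters' processing notes, the tools named are BWA, MACS2, deepTools, DiffBind and HOMER, without versions, and the builds named are hg38 and hg19. The sequence names in all lists carry the contig suffixes used for hg38, and all coordinates here are hg38. The authors called peaks per sample, except in the pooled list. The deposited CTCF and DDIT3-antibody lists, 14 in number, and the pooled list have 10 columns, as in the narrow peak format. The 16 deposited H3K27ac and H3K27me3 lists have 9, as in the broad peak format. In each deposited list the authors gave a score, a fold enrichment over background, a −log10 p and a −log10 q for each peak, and the narrow lists also give the summit offset (a position, not a signal). These values are the authors' own. They were used only to rank or filter peaks within a list, since values from separate lists are not on a common scale. Ranks follow the −log10 q of each list, of which the score is 10 times the value in every list. Which control library entered each call is not given in the sources used here.

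No read counts or totals were used, so the sequencing depth of every library is unknown and no value could be scaled to it. The number of peaks and the base pairs they cover stand in its place as a description of each list.

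Peaks of the lists being compared were merged into regions wherever they shared at least 1 bp, and each region was scored as called or not called in each list. DDIT3-antibody sites of a line are regions called in both replicates of that line and in neither WT list. For CTCF and the histone marks, a gained region was called in both replicates of a line and in neither WT list, and a lost region the reverse. For these counts the 4 lists can also be split by replicate number or crosswise, and those counts stand beside the real ones. With 3 splits a p-value cannot go below 0.333, so none is given. Similarity of lists is the Jaccard index, base pairs shared over base pairs covered by either list. Mean similarity within lines was compared with that between lines by a one-sided exact permutation test over all ways to pair 8 lists. Peak numbers of the DDIT3 antibody were compared by an exact permutation test of the sum of squares between lines of log2 peak number over 15 pairings. Shares of sites in chromatin peaks were compared between a line and WT by a two-sided exact permutation test of 2 against 2 lists, whose smallest possible p is 0.333. Backgrounds for overlaps came from 200 shuffles of the regions within their chromosomes. Shares carry 95% Wilson intervals, which cover counting error only.

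No reference genome and no strand were used here. Gene positions came from a RefSeq table of GRCh38.p14 with 20037 protein-coding genes on the assembled chromosomes. Transcription start sites were therefore replaced by both ends of each gene, a departure from the design as first written. A region is called proximal within 1 kb of a gene end. Exons, introns and untranslated regions were not annotated. The motif comparisons planned at sites and in gained H3K27ac regions, with 13 motifs, need sequence and were not run. Gene names come from the nearest gene end. Members of the fixed gene lists are instead named wherever a region lies within the stated distance of an end, also where another gene is nearer. Neither shows which gene a region regulates.

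Before the data were examined, 12 gene lists were fixed with 4 to 30 members each (260 entries, 260 matched to the table): transgene genes, integrated stress and unfolded protein response, bZIP transcription factors, adipocyte genes, inflammatory and secreted factors, EWS-FLI1 target genes, mesenchymal and matrix genes, polycomb-bound developmental genes, cell cycle genes, housekeeping genes, epithelial markers and blood cell markers. The last 2 stand for cell types that a fibrosarcoma culture should not hold. Members with a site, or with a gained or lost region, within 10 kb of an end were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, over both site sets or over all lines, marks and directions, at a threshold of 0.05. Neighbouring genes can share a region, so genes are not fully independent in these tests. An odds ratio with an empty cell was computed with 0.5 added to each cell.

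The rule for named genes was also fixed before the data were examined. It takes the 15 sites of each set with the best mean rank in both replicates and a gene end within 10 kb, up to 4 examples per gene list by the same rank, the 8 widest gained and lost H3K27ac and H3K27me3 regions per line within 1 kb of a gene end, list members at such regions, the 4 construct genes in every list, and the 15 best-ranked regions of the pooled list with a gene end within 10 kb. Genes named outside this rule were not chosen beforehand, among them HSPA5 at the sites and the genes at sites in gained H3K27ac regions.

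Comparisons of lines that share the WT lists were set beside the overlap of 100 simulated unchanged lines against the same WT lists and beside the overlap expected of independent sets. Alternatives were a 50% reciprocal overlap, the best-ranked 50% of each list by −log10 q, equally long lists (5258 peaks for the DDIT3 antibody, 110797 for CTCF, 44935 for H3K27ac and 85032 for H3K27me3), other windows (1 kb and 50 kb), other backgrounds, WT calls kept, a −log10 q of at least 10 for peak numbers, the replicate number as a block, and leaving out each line or list in turn. For the DDIT3 antibody the length was that of the shortest construct list. WT replicate 1 was cut to it, and WT replicate 2 kept its 453 peaks.

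The scripts were tested on simulated lists. In a simulated DDIT3 line against WT, 300 of 300 planted sites were recovered and 300 sites were returned. The other simulated calls were placed so that they could not coincide between lists. This checks the code and does not measure how often calls of long real lists overlap by chance. Of 20 simulated sets of 8 lists without any effect, 1 reached p = 0.05 or less in the exact permutation test of similarity. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and interval code was checked against bedtools 2.31.1.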

Results

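Peaks of 4 antibodies were recorded in HT1080, a human fibrosarcoma cell line, as parental cells (WT) and as transfected clones carrying EGFP-tagged DDIT3, FUS-DDIT3 or EWS-FLI1. DDIT3, also called CHOP, is a stress-induced bZIP transcription factor. FUS-DDIT3 is the fusion oncoprotein of myxoid liposarcoma, and EWS-FLI1 is that of Ewing sarcoma. The DDIT3 antibody was used in the DDIT3, FUS-DDIT3 and WT lines, and antibodies to CTCF, an insulator protein, to H3K27ac, a histone mark of active promoters and enhancers, and to H3K27me3, the polycomb mark, were used in all 4 lines. Each of the 15 groups had 2 replicates. Lists held 110797 to 131697 CTCF peaks, 44935 to 66778 H3K27ac peaks and 85032 to 141329 H3K27me3 peaks. The sequencing depth is unknown for every library, so a region without a peak is not shown to lack the protein or mark. All positions are on GRCh38.

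The first comparison asked how many regions the DDIT3 antibody marked in each line. In the DDIT3 line replicate 1 had 109666 peaks and replicate 2 had 5258. The FUS-DDIT3 line had 222425 and 12004 peaks, and WT cells, which carry no construct, had 43221 and 453. The longer list was 20.9 times as long as the shorter in the DDIT3 line, 18.5 times in the FUS-DDIT3 line and 95.4 times in WT. In both replicate numbers the FUS-DDIT3 list was the longest and the WT list the shortest. An exact permutation test of log2 peak number over 15 pairings gave p = 0.60 and cannot go below 0.0667, so it could not have shown a difference between lines. With a −log10 q of at least 10 the lists held 18565 and 1112 peaks in the DDIT3 line, 11090 and 4674 in the FUS-DDIT3 line, and 858 and 30 in WT.

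**Figure D1:**
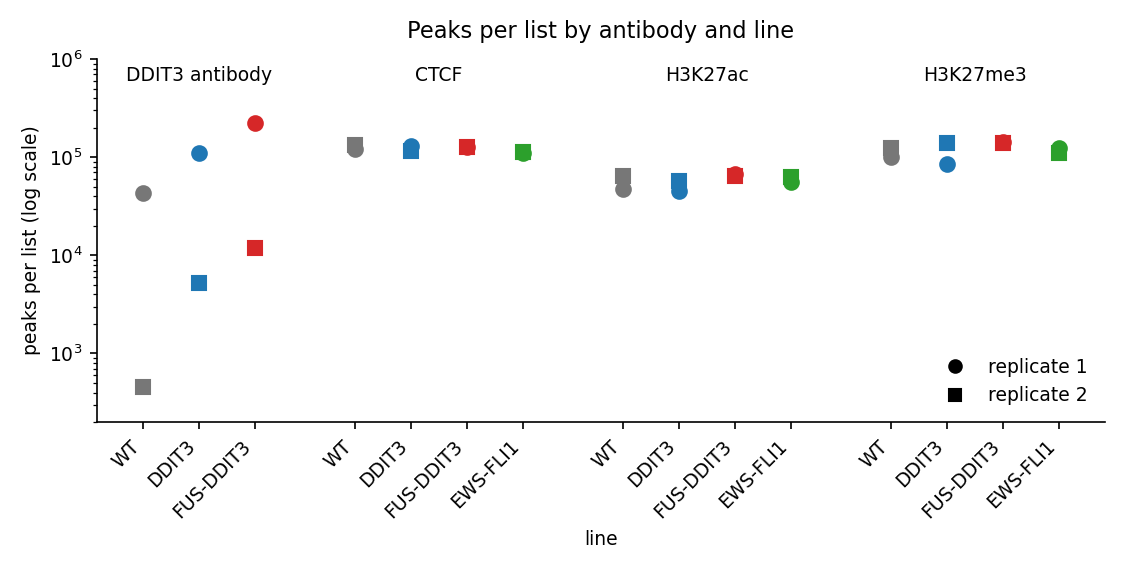
Peaks per list (log scale) for each antibody and line, with a circle for replicate 1 and a square for replicate 2. The DDIT3-antibody lists spread from 453 to 222425 peaks and replicate 1 is the longer list in all 3 lines, whereas CTCF lists lie between 110797 and 131697.

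Regions called in both replicates of a line and in neither WT list were taken as its sites, to ask where the DDIT3 antibody marked chromatin in cells with a DDIT3 or FUS-DDIT3 construct. At the DDIT3 gene itself, on chromosome 12, a peak at 57520417 to 57521061 spanned 1 end of DDIT3 and of its neighbour MBD6, with fold enrichments of 92.5 and 20.6 in replicates 1 and 2 of the DDIT3 line. Cells with FUS-DDIT3 had a peak beside DDIT3 with fold enrichments of 42.3 and 47.8, and neither WT list had a peak within 1 kb of DDIT3. FUS had peaks in DDIT3 replicate 1 and in both FUS-DDIT3 lists, with best ranks of 4927, 18384 and 7182, and none in WT. EWSR1 had peaks in replicate 1 of the DDIT3, FUS-DDIT3 and WT lines, with best ranks of 13845, 6197 and 8564. FLI1 had peaks in the same 3 lists and in FUS-DDIT3 replicate 2, with best ranks of 13399, 37451, 24153 and 9603. All 4 construct genes overlapped H3K27ac peaks in 8 of 8 lists, WT included.

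In the DDIT3 line 2933 regions were sites. Among the best-ranked, MKNK2, a kinase acting on a translation initiation factor, had a site 8148 bp from its end (chromosome 19, 2059392 to 2060166) with fold enrichments of 84.7 and 24.7. IARS1 and AARS1, aminoacyl-tRNA synthetases of the cytosol, had fold enrichments of 92.4 and 30.4 (chromosome 9, 92293456 to 92294036) and of 39.1 and 37.9 (chromosome 16, 70289141 to 70289862). XPOT, which exports tRNA from the nucleus, had 71.2 and 20.4 (chromosome 12, 64404161 to 64405279), and HSPA9, a mitochondrial chaperone, had 54.2 and 16.6 (chromosome 5, 138575058 to 138575989). SESN2, a stress-induced inhibitor of growth signalling, had 59.7 and 25.7 (chromosome 1, 28259005 to 28260744). CEBPG, a bZIP partner of DDIT3, had 72.6 and 12.8 (chromosome 19, 33373358 to 33374360). The other best-ranked sites lay near LOC124902669, DDIT3, IRF2BP2, NFE2L1, STK40, CBX4, LARP6 and GET4. HSPA5, the main chaperone of the endoplasmic reticulum, is named outside the rule fixed beforehand. It ranked 2 in replicate 2 with a fold enrichment of 46.1 but 5135 in replicate 1 with 9.48. Some strong regions were not counted as sites because a WT list called them, and the genes named here were chosen after their values were seen: TRIB3, a stress-induced pseudokinase, had the top rank in both lists of the DDIT3 line (fold enrichments of 110 and 80.8, chromosome 20, 380697 to 382209), with 7.79 in WT replicate 2. PREPL, a hydrolase, and CHAC1, a glutathione-degrading enzyme, were removed likewise.

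The DDIT3 sites had a median width of 512 bp, and 70.2% overlapped a gene. Of the replicate 2 peaks in the DDIT3 line, 66.2% overlapped a replicate 1 peak. Before WT calls were removed 3375 regions were shared. The reverse comparison, called in both WT lists and in neither DDIT3 list, gave 5 regions. WT replicate 2 held 453 peaks and 46 WT replicate 1 peaks overlapped it, so this count could not have been large. Splitting the lists by replicate number gave 4153 regions called in both replicate 1 lists alone and 32 in both replicate 2 lists alone, and the crosswise splits gave 73 and 22, so the split by replicate number returned more regions than the real one. The counts of 32 and 73 need a call in WT replicate 2, so that short list limits them too. Replicate 2 limited the number of sites: without it 104666 regions would count. At equal list lengths 1537 sites were left, in the best-ranked 50% of each list 1462, and with a 50% reciprocal overlap 972.

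In the FUS-DDIT3 line 3252 regions were sites. CEBPG ranked 1 in replicate 1, with fold enrichments of 49.8 and 18.5, and XPOT had 53.2 and 48.9. IARS1 had fold enrichments of 73.6 and 27.8 and AARS1 had 57.5 and 38.8. HSPA5, also named outside that rule here, ranked 1 in replicate 2 (fold enrichments of 13.5 and 74.1), at 125243245 to 125243686 on chromosome 9. SERPINB8, a protease inhibitor, had 40.9 and 46.1, and EHF, an ETS factor of epithelia, had 19.8 and 45.5. The other best-ranked sites lay near LOC124902669, MBD6, CUEDC1, IRF2BP2, MKNK2, HSPA9, STK40, SESN2 and NFE2L1. All 15 best-ranked sites of each line were also sites of the other line and lay in H3K27ac peaks of both their own and both WT lists. The sites had a median width of 347 bp, and 53.1% overlapped a gene. Of the replicate 2 peaks 30.3% overlapped a replicate 1 peak. The region at TRIB3 that WT replicate 2 called ranked 4 and 3 here. Before WT calls were removed 3583 regions were shared, and the reverse comparison with WT gave 5, again limited by the short WT replicate 2 list. The split by replicate number gave 15041 regions called in both replicate 1 lists alone and 8 in both replicate 2 lists alone, against 40 and 54 crosswise, so again it returned more than the real split. The counts of 8 and 40 need a call in WT replicate 2 and are limited likewise. Without replicate 2 the count was 206342, and at equal list lengths, in the best-ranked 50% and with a 50% reciprocal overlap it was 1004, 1763 and 2085.

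The sites of the DDIT3 and FUS-DDIT3 lines differed in how often they lay at gene ends. Within 1 kb of a gene end lay 44.4% of the DDIT3 sites (95% Wilson interval 42.6 to 46.2) and 18.9% of the FUS-DDIT3 sites (17.6 to 20.3), an odds ratio of 3.41 (two-sided Fisher's exact test, p = 1.59e-104). That test treats sites as independent and leaves out the spread between replicates. Among the 1000 best-ranked peaks the share was 55.4% and 18.5% in the 2 DDIT3 lists, 19.5% and 5.2% in the FUS-DDIT3 lists, and 6.4% in WT replicate 1, so the DDIT3 list had the larger share in both replicate numbers, and replicate 1 the larger share in both construct lines. Of the 453 best-ranked WT peaks 8.17% lay there in replicate 1 and 17.7% in replicate 2, the latter above the 13.5% and 6.62% of replicate 2 in the DDIT3 and FUS-DDIT3 lines. Genes with a site within 10 kb numbered 2730 of 20037 (13.6%) for DDIT3 and 1719 (8.58%) for FUS-DDIT3.

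Members of the integrated stress and unfolded protein response lay near sites in both lines. Of the 28 genes 19 had a DDIT3 site within 10 kb (odds ratio 13.5, Benjamini-Hochberg adjusted p = 8.12e-10) and 17 had a FUS-DDIT3 site (odds ratio 16.6, adjusted p = 1.41e-10), both by two-sided Fisher's exact tests over 24 list and line pairs. Near DDIT3 sites TNFRSF10B, a death receptor, had fold enrichments of 66.2 and 16.0 (chromosome 8, 23068495 to 23069389). HERPUD1, which helps degrade misfolded proteins, had 49.7 and 13.9 (chromosome 16, 56931540 to 56932655), and a second region near TRIB3, not called in WT, had 37.0 and 18.0 (chromosome 20, 371692 to 372259). Near FUS-DDIT3 sites PPP1R15A, a phosphatase subunit that restores translation after stress, had 30.4 and 19.2 (chromosome 19, 48874963 to 48875841), TNFRSF10B had 31.7 and 17.6, and SARS1, the seryl-tRNA synthetase, had 17.0 and 29.6. Of the 28 genes 15 had a site in both lines. ATF4, a stress-response factor, SLC7A11, a cystine transporter, STC2 and VEGFA, an angiogenic factor, had one in the DDIT3 line alone, CHAC1 and VLDLR in the FUS-DDIT3 line alone, and 7, among them ASNS and ATF3, in neither. The ATF4 site lay 6539 bp from an end of ATF4 and overlapped RPS19BP1. FUS-DDIT3 replicate 1 also called the sites near ATF4 and VEGFA, and its replicate 2 the one near SLC7A11. DDIT3 replicate 1 called the VLDLR site, while neither FUS-DDIT3 list called the STC2 site. CHAC1 also had a region called in both lists of the DDIT3 line, at ranks 44 and 205, which is not counted because WT replicate 1 called it at rank 8943. Whether the lines differ here was not tested.

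The bZIP transcription factors, possible dimer partners of DDIT3, also lay near sites more often than other genes. Of 28 genes 11 had a DDIT3 site (odds ratio 4.11, Fisher's exact test, adjusted p = 0.00405) and 9 a FUS-DDIT3 site (odds ratio 5.07, adjusted p = 0.00302), and 7 had both. CEBPB, a regulator of adipocyte and inflammatory genes, had fold enrichments of 24.4 and 34.3 in the DDIT3 line (chromosome 20, 50192268 to 50192593) and of 27 and 26.9 in the FUS-DDIT3 line. NFE2L2, the main antioxidant response factor, had 18.0 and 10.2 and MAFG, its partner, had 22.4 and 5.15 in the DDIT3 line. The MAFG site lay 5333 bp from an end of MAFG and overlapped PYCR1. With FUS-DDIT3 ATF5 had 20.1 and 8.16 and FOSL1 had 4.73 and 5.73. The ATF5 site lay 4233 bp from an end of ATF5 and overlapped IL4I1 and NUP62. For FUS-DDIT3 the bZIP list missed the threshold within 1 kb of a gene end (odds ratio 4.43, Fisher's exact test, adjusted p = 0.107). Without replicate 2 neither list passed Fisher's exact test at DDIT3 sites (odds ratio 11.1 and adjusted p = 0.101 for each) or at FUS-DDIT3 sites (odds ratio 4.51 and adjusted p = 0.633 for each), when 104666 and 206342 regions count as sites. So many sites reach many genes of any list, so these tests cannot show that an enrichment was lost.

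The other 10 lists did not pass the threshold by Fisher's exact test in either line. Of adipocyte genes 4 of 25 had a DDIT3 site, PLIN2 and SCD among them, and 1 of 25, PLIN2, a FUS-DDIT3 site. Of inflammatory and secreted factors 5 of 24 had a site in each line, HMOX1 and SERPINE1 in both, with an adjusted p of 0.239 at FUS-DDIT3 sites that became 0.0194 without replicate 1 (odds ratio 3.47). EWS-FLI1 target genes counted 4 and 1 of 28, mesenchymal and matrix genes 1 and 3 of 26, polycomb-bound developmental genes 4 and 1 of 30, cell cycle genes 6 and 3 of 25, housekeeping genes 4 and 3 of 18, and transgene genes 1 and 1 of 4, DDIT3 itself. Epithelial markers, which stand for cells a fibrosarcoma culture should not hold, counted 2 and 3 of 12, and blood cell markers 3 and 2 of 12.

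**Figure D2:**
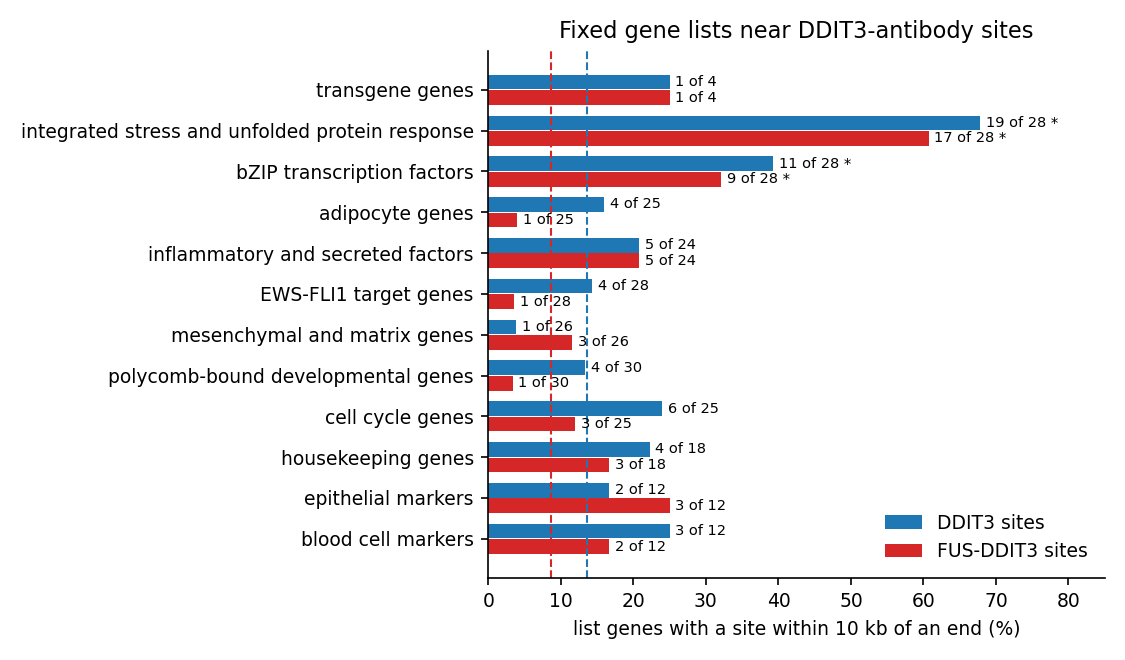
Percentage of each fixed gene list with a site within 10 kb of a gene end, for DDIT3 sites and FUS-DDIT3 sites, with the counts beside the bars, a dashed line at the share of other protein-coding genes and a star where the Benjamini-Hochberg adjusted p of Fisher's exact test is below 0.05. The stress response list stands highest with 19 of 28 and 17 of 28 genes.

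Whether the DDIT3 antibody marked the DDIT3 and FUS-DDIT3 lines at the same places was asked next. The lists do not separate endogenous DDIT3 in the clones from the constructs, and no DDIT3-antibody list exists for the EWS-FLI1 line, transfected without a DDIT3 construct. Of the DDIT3 sites 1029, or 35.1% (95% Wilson interval 33.4 to 36.8), overlapped a FUS-DDIT3 site, and of the FUS-DDIT3 sites 1030, or 31.7% (30.1 to 33.3), overlapped a DDIT3 site. Over the merged regions of all lists 954 held both, against 13.8 expected of independent sets (odds ratio 167, 95% interval 152 to 183, with a Fisher's exact p below the smallest number the software holds). Among regions of the DDIT3-antibody and WT H3K27ac lists alone 1000 held both against 26.2 expected (odds ratio 89.7, 82.0 to 98.1). Independent simulated lists shared at most 9 and 39 regions. Each of those lists had the same call rate in all regions, and replicates were drawn independently. They leave out that most sites of both lines lay in H3K27ac peaks, as does the independent expectation, so both are easily exceeded. No peak in either list of the other line overlapped 17.8% of the DDIT3 sites and 19.0% of the FUS-DDIT3 sites. Shared DDIT3 sites lay at gene ends in 25.9% and the rest in 54.3%, while for FUS-DDIT3 the shares were 25.6% and 15.8%. Without replicate 2 the odds ratio was 1.15.

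Chromatin at the sites was asked about in each line. DDIT3 sites overlapped H3K27ac peaks in 90.4% ± 4.29 of cases in the DDIT3 line and 87.4% ± 3.16 in WT (SD, n = 2, two-sided exact permutation p = 0.667). FUS-DDIT3 sites overlapped them in 85.7% ± 1.57 in the FUS-DDIT3 line and 78.4% ± 3.52 in WT (SD, n = 2, exact p = 0.333, the smallest that 2 lists against 2 allow). The shares in the own line were 22.5 and 19.6 times those of shuffled sites, and 4.12 and 3.23 times those of CTCF regions. The regions at SESN2, CEBPG, IARS1 and HSPA5 were all in H3K27ac peaks of WT cells. CTCF peaks overlapped 54.0% ± 8.20 of the DDIT3 sites in the DDIT3 line against 62.9% ± 10.8 in WT (SD, n = 2, exact p = 0.667), and 35.6% ± 2.37 of the FUS-DDIT3 sites in their line against 43.6% ± 9.24 in WT (SD, n = 2, exact p = 0.667). H3K27me3 peaks overlapped 0.972% ± 0.169 of the DDIT3 sites in the DDIT3 line and 8.25% ± 8.92 in WT (SD, n = 2, exact p = 0.333). At FUS-DDIT3 sites the H3K27me3 shares were 7.07% ± 5.52 and 6.84% ± 4.33 (SD, n = 2, exact permutation p = 1.0). The ratio of the mean H3K27me3 share in the own line to that of shuffled sites was 0.0754 for DDIT3 sites and 0.772 for FUS-DDIT3 sites, and over single lists of all lines it ran from 0.0314 (FUS-DDIT3 replicate 2) to 1.2998 (WT replicate 2) and from 0.224 (DDIT3 replicate 2) to 0.985 (WT replicate 2). An exact test of 2 lists against 2 cannot reach p = 0.05, so none of these differences could pass.

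**Figure D3:**
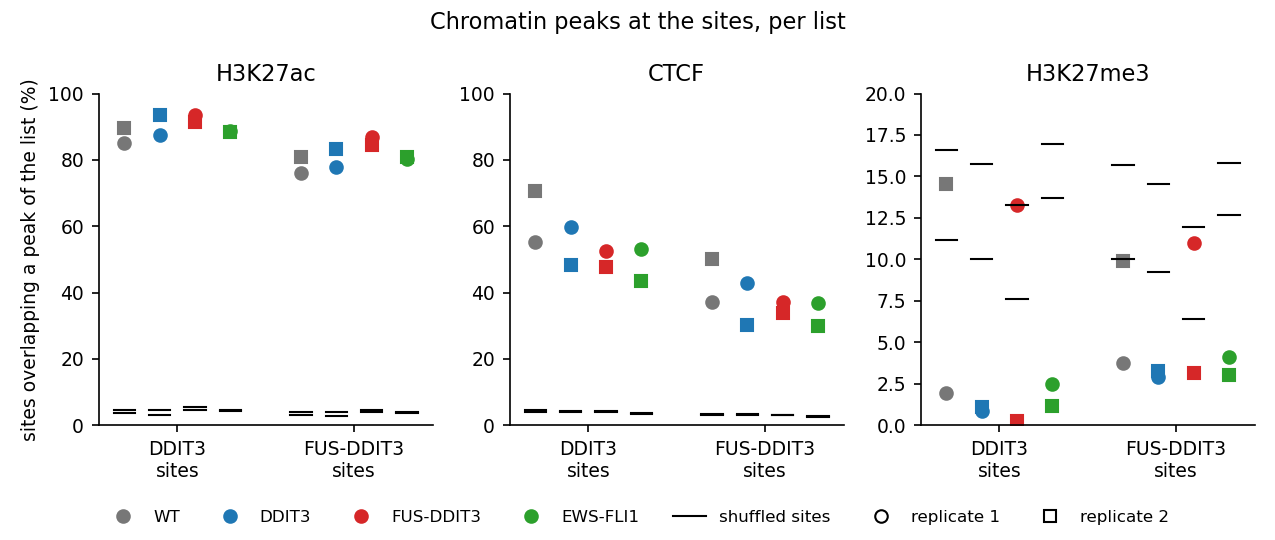
Percentage of DDIT3 sites and FUS-DDIT3 sites that overlap a peak of each H3K27ac, CTCF and H3K27me3 list, by line (colour) and replicate (circle or square), with black bars at the mean of shuffled sites. The H3K27ac shares lie between 75.9 and 93.5% in all 4 lines, and the H3K27me3 panel has a shorter axis.

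A list of the DDIT3 antibody in the DDIT3 line that was deposited as pooled also had regions near stress response genes. It held 1200 regions, and the best-ranked with a gene end within 10 kb lay at TRIB3, MKNK2, PREPL, IARS1, CEBPG, IRF2BP2, XPOT and HSPA5, with fold enrichments of 19.3, 24.1, 20.2, 15.8, 12.4, 17.5, 10.4 and 22. LOC124902669, HSPA9, SESN2, MBD6, OR2S2, CBX4 and HERPUD1 followed. Near its regions lay 16 of 28 stress response genes (odds ratio 40.8, Fisher's exact test, Benjamini-Hochberg adjusted p = 3.11e-16) and 5 of 28 bZIP genes (odds ratio 6.54, adjusted p = 0.0112), and none of the other lists passed. Of the regions 71.8% overlapped DDIT3 replicate 1, 63.5% replicate 2 and 83.6% (95% Wilson interval 81.4 to 85.6) either, against 3.0% and 0.667% for the WT lists. They overlapped the FUS-DDIT3 lists in 79.3% and 57.4%. All 1200 of its peak names carry the name of the replicate 2 library and none that of replicate 1. Which libraries were pooled, and whether several were, is not given in the sources used here, so this list is not an independent replicate.

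Whether lists of a line resembled each other more than lists of other lines was asked for each mark. H3K27ac lists of the same line had a Jaccard index of 0.597 ± 0.113 (SD, n = 4 pairs) and those of different lines 0.532 ± 0.0953 (n = 24 pairs), and 2 of the possible pairings, the real one included, gave as large a difference (one-sided exact permutation p = 0.019, smallest possible 0.00952). CTCF had 0.602 ± 0.0186 within lines and 0.591 ± 0.0473 between them (exact permutation p = 0.229), a difference of 0.0111 that ran from −0.00179 (without WT replicate 2) to 0.0295 (without EWS-FLI1 replicate 1) with 1 list left out. H3K27me3 had 0.403 ± 0.157 and 0.346 ± 0.122 (exact permutation p = 0.0857). Some lists stood apart: DDIT3 replicate 1 for H3K27ac had a mean index of 0.396 with the other lists, and FUS-DDIT3 replicate 2 for H3K27me3 had 0.173. The H3K27ac difference of 0.0648 missed the threshold when either FUS-DDIT3 list, either EWS-FLI1 list or WT replicate 1 was left out, down to 0.0428 without EWS-FLI1 replicate 1 (exact permutation p = 0.143), and was 0.122 without DDIT3 replicate 2 (exact p = 0.019). For H3K27me3 the difference of 0.0568 became 0.00887 without EWS-FLI1 replicate 2 (exact permutation p = 0.362) and 0.142 without FUS-DDIT3 replicate 1 (exact p = 0.00952).

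**Figure D4:**
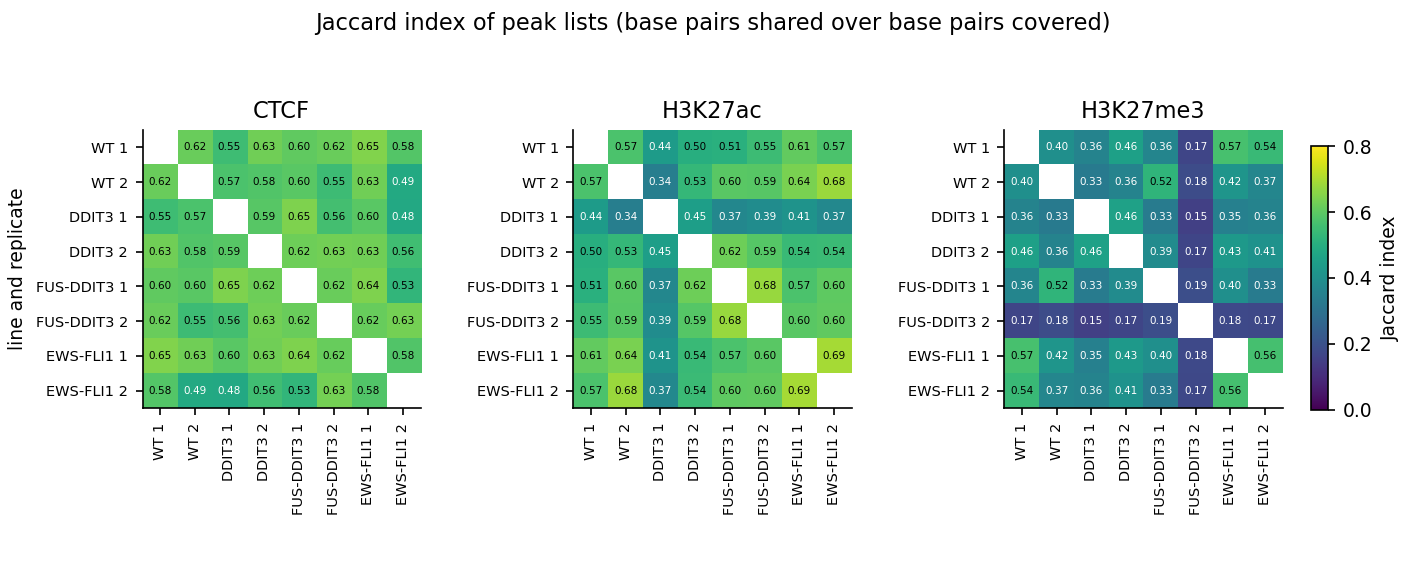
Jaccard index of each pair of lists, as base pairs shared over base pairs covered by either, for CTCF, H3K27ac and H3K27me3, with lists ordered by line and replicate. The darkest bands, which mark low values, are DDIT3 replicate 1 for H3K27ac, with a mean of 0.396, and FUS-DDIT3 replicate 2 for H3K27me3, with a mean of 0.173.

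H3K27ac was then compared with WT to ask which active regions each construct line gained or lost, and the widest changes near gene ends are named. For this and the other marks, the construct lines differ from parental cells also as transfected clones grown with G418. Such effects cannot be told apart from those of the construct. In the DDIT3 line 3487 regions were gained and 5971 lost. Gained regions included 33.8 kb at CELF2, an RNA-splicing regulator (chromosome 10, 11314508 to 11348299), 7.61 kb at ZNF283 and 6.57 kb at ZNF404, both zinc-finger genes, and 5.29 kb at TBC1D14, an autophagy regulator. FAM210A, GUK1, TMEM278 and ABCA7 followed. Lost regions included 6.10 kb at XDH, an enzyme of purine breakdown (chromosome 2, 31333567 to 31339665), 4.41 kb at BCL2A1, an inhibitor of apoptosis, 3.70 kb at SNAI2, a regulator of mesenchymal identity (chromosome 8, 48918666 to 48922364), and 3.56 kb at LCP1, an actin-bundling protein of blood cells. CCNY, FAM20C, TNFRSF19 and TFAP2C followed. Of the fixed lists ICAM1, FOSL2 and the housekeeping genes RPL13A and UBC had gained regions at an end, and COL1A2, CSF2, CD14 and PPIA had lost ones. All 8 of the widest lost regions were called in 4 of the 4 H3K27ac lists of the other 2 construct lines. Without DDIT3 replicate 1, the H3K27ac list that stood apart, 12081 regions were gained and 6591 lost, and without replicate 2 11068 were gained and 13994 lost. The split by replicate number gave 5959 regions in all against 9458 for the real split, and the crosswise split 796.

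The FUS-DDIT3 line gained 7365 H3K27ac regions and lost 2256. LRRC38 gained 6.72 kb, CDH11, a cadherin of mesenchymal cells, gained 6.38 kb (chromosome 16, 65117852 to 65124235), and ZNF404 and CELF2 gained 5.62 and 4.60 kb. PPP1R14C, PSG1, a pregnancy-specific glycoprotein, WNT9A, a signalling ligand, and DCSTAMP, a cell-fusion protein of osteoclasts, also gained regions. ZNF804A lost 2.85 kb, SLC1A3, a glutamate transporter, 2.83 kb, SOX7, a transcription factor of vessels, 2.56 kb, and CGAS, a sensor of cytosolic DNA, 2.16 kb. MDGA2, ADGRL3, ZGLP1 and PDE3A also lost regions. Of the fixed lists ACACA, CCL2, GATA4, OLIG2, HOXB13 and RPL13A gained regions, and CSF2, COL1A2, PPIA and CD14 lost them. Splits by replicate number and crosswise gave 1901 and 3055 regions in all against 9621. Without FUS-DDIT3 replicate 2 the gained regions were 15576, without WT replicate 1 the lost ones were 11297, and at equal list lengths 3632 were gained and 3034 lost.

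In the EWS-FLI1 line 2842 H3K27ac regions were gained and 1516 lost. SLC24A3, a sodium and calcium exchanger, gained 14 kb (chromosome 20, 19210112 to 19224077). XAGE1B and XAGE1A, cancer-testis genes of near-identical sequence, which limits how reads are assigned to either, gained 10.9 and 9.54 kb. TPSAB1 and TPSG1, tryptase genes, gained 8.31 and 4.75 kb, and SAG, TMEM233 and CDH11 also gained regions. NKX2-2, a homeobox gene known as a target of EWS-FLI1 in Ewing sarcoma, gained 2.21 kb (chromosome 20, 21520921 to 21523126), and was the 1 gene of the 28 EWS-FLI1 targets with a gained region at an end. ICAM1 gained 1.02 kb. ZNF804A, SOX7 and CGAS lost the same regions as in the FUS-DDIT3 line, and WT1, a developmental transcription factor, lost 1.85 kb. No H3K27ac list of the DDIT3 line called the regions at SOX7 and CGAS either, so these losses were not limited to the fusion lines. The region at ZNF804A was called in 1 list of the DDIT3 line. GABBR2, PODXL, CCN5 and SMOC1 also lost regions. The split by replicate number gave 4857 regions in all, more than the 4358 of the real split, and the crosswise split 1761. Without WT replicate 2 the gained regions were 10201, without WT replicate 1 the lost ones were 9933, and at equal list lengths 1681 were gained and 1686 lost.

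H3K27me3 was compared with WT in the same way for the polycomb mark. In the DDIT3 line 9597 regions were gained and 9530 lost. PXDN, a peroxidase of the extracellular matrix, gained 23.3 kb (chromosome 2, 1726854 to 1750115) and COBL, an actin nucleator, gained 19.5 kb, with GABRA5, TMEM132D, GALNT17, ATP13A5, NEBL and ATP10A beside them. A region of 90.1 kb at PPP2CB and TEX15 was lost (chromosome 8, 30813678 to 30903803), and SPTB, PURG, VSIG10L2, TEX15, KLF14, ADARB2 and IFNA21 lost 28.2 to 48.6 kb. Among adipocyte genes 5 of 25 had a lost region at an end: PPARG, the master regulator of fat cell formation, with 8.0 kb (chromosome 3, 12428667 to 12436666), KLF15 with 6.27 kb, PLIN1, GPD1 and PLIN4. Among epithelial markers 3 of 12 did, ESRP1 with 15.5 kb, GRHL2 and ELF3. FLI1, GATA4, HOXC13 and CD79A also had lost regions at an end, and VLDLR a gained one. The list tests over genes did not pass for any of these groups. Splits by replicate number and crosswise gave 4507 and 9237 regions in all against 19127. Without DDIT3 replicate 1 the gained regions were 49385, and without WT replicate 2 the lost ones were 34785.

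In the FUS-DDIT3 line 5817 H3K27me3 regions were gained and 5769 lost. PXDN gained 11.9 kb and COBL 6.87 kb, at places that were also gained in the DDIT3 line, and CXCL12, a chemokine, gained 11.5 kb (chromosome 10, 44383691 to 44395176). The PXDN region was called in 4 lists of the other construct lines, those of EWS-FLI1 included, and the COBL region in 3. LOC101060212, MUC16, TMEM132C, TNS3 and OR7G2 gained regions too. ADARB2 lost 29.0 kb, as in the DDIT3 line, and DOCK3, ILDR2, KLRB1, OR4N5, DAAM2, ENTREP1 and ONECUT2 lost 10.3 to 25.3 kb. GATA4 and HOXC13, developmental regulators, lost the same regions in both lines. The crosswise split gave 15219 regions in all, more than the 11586 of the real split, and the split by replicate number 5383. Without FUS-DDIT3 replicate 2, the list that stood apart, 43728 regions were gained and 8150 lost, and without replicate 1 53492 were gained and 19697 lost. Without WT replicate 2 36816 were lost, and at equal list lengths 2452 were gained and 6751 lost.

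In the EWS-FLI1 line 6929 H3K27me3 regions were gained and 3270 lost. ELOVL2, an enzyme elongating fatty acids, gained 8.60 kb (chromosome 6, 10975586 to 10984184), and LGR5, a stem cell receptor, gained 5.41 kb. EIF2S3B, SLC38A1, GABRG3, HYKK, GBP7 and XYLT2 gained 4.55 to 8.60 kb. AQP4, a water channel, lost 6.04 kb (chromosome 18, 26845856 to 26851897) and SST, the somatostatin gene, lost 4.14 kb, with MYL10, JAKMIP2, CNTNAP2, CD37, PSG3 and ACSF2 beside them. ATF3, EPCAM and CD19 had a gained region at an end. Splits by replicate number and crosswise gave 6201 and 7775 regions in all against 10199. Without EWS-FLI1 replicate 2 the gained regions were 30630, without WT replicate 2 the lost ones were 21931, and at equal list lengths 4204 were gained and 3070 lost.

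CTCF peaks were compared with WT to ask whether insulator sites differed. The DDIT3 line gained 5546 regions and lost 6071, the FUS-DDIT3 line gained 7146 and lost 4709, and the EWS-FLI1 line gained 1838 and lost 6270. Regions called in all 4 lists of a line and WT numbered 82805, 87805 and 84842. Splits by replicate number gave 3520, 4026 and 3460 regions in all, and crosswise splits gave 9685, 8104 and 8139, against 11617, 11855 and 8108, so in the EWS-FLI1 line the crosswise split returned more than the real one. Of the changed regions few lay in the best-ranked 50% of the lists that called them: 217 gained and 133 lost in the DDIT3 line, 129 and 39 in the FUS-DDIT3 line, and 3 and 43 in the EWS-FLI1 line. Without 1 list counts rose to as many as 23062 gained in the DDIT3 line (without its replicate 2), 18090 in the FUS-DDIT3 line (without its replicate 2) and 7723 in the EWS-FLI1 line (without its replicate 1). Without WT replicate 1 the lost regions were 21577, 21512 and 25965, and at equal list lengths the EWS-FLI1 line gained 2858 and lost 3126.

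**Figure D5:**
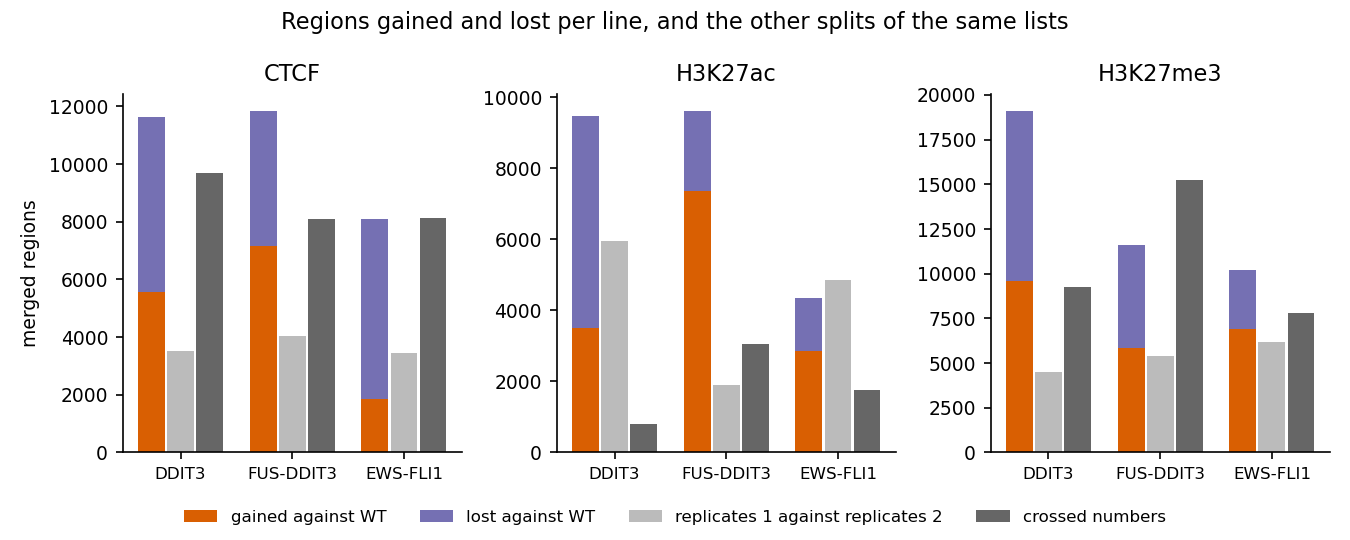
Regions gained and lost against WT for CTCF, H3K27ac and H3K27me3 in each construct line, stacked for the real split of the 4 lists, the split by replicate number and the crosswise split. Of the 9 real totals 3 are exceeded by another split: CTCF and H3K27ac in the EWS-FLI1 line, with 8108 and 4358, and H3K27me3 in the FUS-DDIT3 line, with 11586.

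No fixed gene list gathered at gained or lost H3K27ac or H3K27me3 regions after adjustment. Of 144 Fisher's exact tests 0 had a Benjamini-Hochberg adjusted p below 0.05 and 1 had an unadjusted p below 0.05, where chance gives at most 7.2 on average, and fewer with lists this short. That test was for polycomb-bound developmental genes at lost H3K27ac in the EWS-FLI1 line, where HOXA9, HOXD8, HOXD10, HOXD13 and WT1, 5 of 30 genes, had a lost region within 10 kb (odds ratio 8.31, Fisher's exact test, adjusted p = 0.0922, and 0.00768 adjusted over the list alone). With 1 list left out up to 3 tests passed. Without WT replicate 1 these Fisher's exact tests were for inflammatory and secreted factors at lost H3K27ac in the DDIT3 line (11 of 24 genes, adjusted p = 0.0413) and in the EWS-FLI1 line (9 of 24, adjusted p = 0.0413), and polycomb-bound genes at lost H3K27me3 in the EWS-FLI1 line (18 of 30, adjusted p = 0.0498). Without replicate 1 of the line the last had 10 of 30 genes (Fisher's exact test, adjusted p = 0.0444), and without replicate 2 of the line housekeeping genes passed at gained H3K27ac in the DDIT3 line (12 of 18, adjusted p = 0.00967).

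Whether H3K27ac was gained at the sites themselves was also asked. In the DDIT3 line 76 of 2710 H3K27ac regions with a site were gained, an odds ratio of 0.676 against all other regions (95% interval 0.537 to 0.852, two-sided Fisher's exact p = 0.000519). In the FUS-DDIT3 line 111 of 2735 were gained, an odds ratio of 0.450 (0.371 to 0.544, Fisher's exact p = 3.35e-20). Of regions with a site 95.2% and 93.3% were in a WT region and could not be gained, which lowers both odds ratios. The best-ranked sites in gained regions of the DDIT3 line lay near KLHDC7B, with fold enrichments of 38.1 and 16.8, MRPL48, a mitochondrial ribosomal protein, PLTP, a phospholipid transfer protein, FUT3, DOCK1, BMF, which promotes apoptosis, DNAL4 and HNRNPK. Those of the FUS-DDIT3 line lay near MRPL48, with 19.5 and 18.1, KLHDC7B, RHBDF1, DHRS3, UBE2G2, WNT6, TROAP and RNF122. The genes at these sites are named outside the rule fixed beforehand. Against all regions the odds ratio of the DDIT3 line missed the threshold without WT replicate 2 (0.862, Fisher's exact p = 0.0874) and was 0.237 without replicate 2 of the line, and that of the FUS-DDIT3 line was 0.278 without its replicate 2 and 0.288 without its replicate 1.

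The last comparison asked whether lines changed at the same regions. Of H3K27ac regions lost in the DDIT3 and FUS-DDIT3 lines 1757 were lost in both, COL1A2, CSF2, CD14 and PPIA among their genes, against 330 expected of independent sets and 416 in simulated unchanged lines that share the WT lists. Of gained H3K27ac regions 1548 were gained in both, CELF2 and ZNF404 among their genes, against 680 expected and 492 simulated. For H3K27me3 these 2 lines shared 2305 lost regions against 870 expected and 705 simulated, and 1129 gained ones against 328 and 592. For CTCF they shared 2580 lost against 275 expected and 1089 simulated, and 2638 gained against 833 and 670. The DDIT3 and EWS-FLI1 lines shared 940 lost H3K27ac regions, against 217 expected and 416 simulated, and 590 gained ones against 261 and 493. They shared 1212 lost H3K27me3 regions (525 expected, 697 simulated) and 958 gained ones (416 and 591), and 2319 lost CTCF regions (366 and 1088) and 679 gained ones (214 and 672, with a highest simulated value of 738). The FUS-DDIT3 and EWS-FLI1 lines shared 628 lost and 1088 gained H3K27ac regions (83.0 and 534 expected, 415 and 492 simulated), 1001 lost and 652 gained H3K27me3 regions (307 and 230 expected, 707 and 593 simulated, where the highest value for gained regions was 652), and 2420 lost and 938 gained CTCF regions (283 and 275 expected, 1093 and 669 simulated). The simulated lines take the call rate of each region from all 8 lists of the mark, so their overlap does not follow how many regions each line gained or lost. That rate also holds the WT calls by which the regions were picked. These lower it where gains were counted and raise it where losses were counted. The simulated overlaps may therefore be too low, and are no exact measure for unchanged lines. The WT lists were not split between lines, which would leave 1 control list for each, so part of each overlap may come from shared controls. All construct lines are also transfected clones with an EGFP tag, grown with G418 and compared with parental cells. Changes shared by the lines cannot be told apart from effects of these conditions.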

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

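All tests of explanations in this part were chosen only after the result was seen, except the one on how closely the unmatched regions of the pooled list lie together, whose bound was written before its value was computed.

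The sites of the DDIT3 and FUS-DDIT3 lines differed in a test of the difference itself: DDIT3 sites lay within 1 kb of a gene end more often, with an odds ratio of 3.41. Length of the construct lists alone as the cause is argued against, since with these equally long 57.3% of 1537 DDIT3 sites and 13.8% of 1004 FUS-DDIT3 sites lay there (odds ratio 8.36, 95% interval 6.80 to 10.3). The 2 WT lists, the same for both lines, were not equally long there. Differences between single libraries may account for it and cannot be told apart from the lines with 2 lists each: an exact permutation of the shares in the 1000 best-ranked peaks gave p = 0.667 but cannot go below 0.333, so it decides nothing either way. In the 453 best-ranked peaks the DDIT3 list had the larger share in both replicate numbers, 48.8% against 22.1% in replicate 1 and 13.5% against 6.62% in replicate 2, and replicate 1 had the larger share in both lines, but in WT the shares were 8.17% and 17.7%, the larger one in replicate 2. A difference between the proteins in where they bind stays open as well, untested.

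The 3 DDIT3-antibody lists of replicate 1 were many times longer than those of replicate 2, 20.9 times in the DDIT3 line and 18.5 times in the FUS-DDIT3 line. Calls unrelated to acetylated chromatin are argued against as the whole cause, since calls that replicate 2 lacks lay in WT H3K27ac regions 7.57 times as often as shuffled regions in the DDIT3 line (95% interval 7.51 to 7.63) and 2.56 times in the FUS-DDIT3 line (2.53 to 2.60). Weak calls alone stay open: with a −log10 q of at least 10 the replicate 1 list was 16.7 times as long in the DDIT3 line and 2.37 times in the FUS-DDIT3 line, but q values of separate lists of unknown depth are not on a common scale. Signal in open chromatin that needs no construct could account for part: 8.60% of the WT replicate 1 peaks (95% Wilson interval 8.33 to 8.86) but 31.3% of the 453 WT replicate 2 peaks (27.2 to 35.8) lay in WT H3K27ac regions, against 33.0% of the unmatched DDIT3 calls and 10.3% of the unmatched FUS-DDIT3 calls, so the WT lists, the short one added after the longer, leave this undecided. Sequencing depth, control libraries and call settings stay open because no value here measures them, and no biological explanation was tested since the pattern follows the replicate number in all 3 lines.

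Of the pooled DDIT3-antibody list, which no comparison between lines used, 197 regions were in neither DDIT3 replicate list. Calls just past the threshold are argued against, since the median −log10 q of these regions was 5.14 above the lowest of the list (95% interval 4.12 to 5.53). Repeated sequence whose signal differs between libraries may account for them: of those on assembled chromosomes 82.2% lay within 10 kb of another (95% Wilson interval 73.9 to 88.3), against 8.24% of the regions found in either list (6.65 to 10.2). Outside the assembled chromosomes lay 45.7% of the 197 against 5.58% of the others, and 43.7% overlapped H3K27ac of DDIT3 replicate 1 against 2.54% for replicate 2, values that prompted this hypothesis. The repeats themselves were not annotated, so this stays a hypothesis, another control or other call settings stay open since all peak names of this list carry the name of the replicate 2 library and whether several libraries were pooled is not known, and no biological explanation was tested.

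Flagged as a difference between lines was also a ratio of odds ratios of 2.23, DDIT3 over FUS-DDIT3, for H3K27ac regions in no WT list with and without a site, but within such regions a gain only separates calls in both replicates from calls in 1, so the value compares how well replicates agree and does not measure gain against WT.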

How the results depend on the processing

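Of 433 alternatives for 69 results 299 kept the direction and the side of the threshold or stayed within the spread or 1.5 times the count, 114 moved, 15 became weaker, 3 stronger and 2 reversed. Chosen only after the data were seen were 84 of these, namely the crossed replicate block, the background of regions in no WT list, and leaving out single lists for peak number, similarity, chromatin, the pooled list, mark gene lists, H3K27ac gain and lost H3K27ac over gained H3K27me3, as was the addition of 0.5 to tables with an empty cell. The motif comparisons at sites and in gained H3K27ac regions, with their alternatives, were not run, for lack of a genome sequence. Where a value below moved, the cause was not tested, apart from what the construction of the alternative itself gives: a stricter list or shorter lists hold fewer regions, and leaving out a list drops a requirement. Sequencing depth is unknown, which limits every count of regions called in 1 line and not in another.

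Replicate numbers were checked as pairs and are not shown to pair the samples. The check was the correlation between lines, over regions, of the call in replicate 1 minus that in replicate 2 (regions are not independent). For CTCF it ran from 0.133 to 0.176 among the construct lines and −0.124 to −0.0955 between them and WT. It ran from −0.0339 to 0.102 for H3K27ac and −0.107 to 0.0467 for H3K27me3. For the DDIT3 antibody, whose replicate 1 lists were the longer ones in all 3 lines, it ran from −0.505 to −0.168. Regions enter only where a list called them, so long lists with mostly unshared calls push the correlation below 0. Negative values therefore do not speak against pairing, and the check cannot decide it. With the number as a block the exact permutation p was 0.167 for DDIT3-antibody peak numbers, the smallest that this block allows, and similarity differed within lines by 0.0137 for CTCF (exact p = 0.0833), 0.0701 for H3K27ac (exact p = 0.0417) and 0.0468 for H3K27me3 (exact p = 0.208). Counts of sites and of gained and lost regions are identical under the block and the crossed block by construction.

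Sites in the DDIT3 line numbered 972 with a 50% reciprocal overlap, 1462 in the best-ranked 50% and 1537 at equal list lengths, and in the FUS-DDIT3 line 2085, 1763 and 1004. Leaving out 1 list gave 2951 (without WT replicate 2) to 104666 (without replicate 2) in the DDIT3 line and 3285 to 206342 in the FUS-DDIT3 line, likewise. Agreement of the pooled list was 63.5% without replicate 1 and 71.8% without replicate 2. With the centre of the site inside the peak, DDIT3 sites overlapped CTCF in 37.4% and H3K27me3 in 0.716%, and FUS-DDIT3 sites overlapped CTCF in 25.6% and H3K27ac in 83.5%. With marks called in both replicates these shares were 45.7%, 0.341%, 31.2% and 83.2%, and the H3K27me3 share of FUS-DDIT3 sites, 7.07% as reported, was 1.69%. Against CTCF regions the H3K27ac ratios were 4.12 and 3.23 and the H3K27me3 ratio of DDIT3 sites 0.107.

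Gene lists past the threshold numbered 1 at FUS-DDIT3 sites within 1 kb, where the bZIP list had an odds ratio of 4.43 (Fisher's exact test, adjusted p = 0.107). Leaving out a replicate gave 0 lists (without replicate 2) to 2 at DDIT3 sites and 0 to 3 at FUS-DDIT3 sites. Odds ratios of the stress response list ran from 11.1 to 11.4 at DDIT3 sites and from 4.51 to 10.3 at FUS-DDIT3 sites, and those of the bZIP list from 3.47 to 11.1 and from 4.21 to 4.51. Adjusted Fisher's exact p reached 0.101 and 0.633 without replicate 2, where so many regions count as sites that a lost enrichment cannot be read from it. Against regions in no WT list the odds ratios of H3K27ac gain at sites lay on the other side of 1, at 6.53 for DDIT3 and 2.93 for FUS-DDIT3, but there a gain only separates calls in both replicates from calls in 1, so this setting does not test gain against WT. Against all regions, with 1 list left out, the DDIT3 odds ratio ran from 0.237 (without replicate 2 of the line) to 0.862 (without WT replicate 2), and the FUS-DDIT3 one from 0.278 to 0.484. With a gain in any replicate of the line counted, both fell below these ranges. In the DDIT3 line 131 of 2710 regions with a site and 19531 of 83384 without a site were then gained. For the FUS-DDIT3 line these counts were 182 of 2735 and 20864 of 84353. Every region in no WT list counts as gained in this setting. It therefore restates how often regions with a site lay in a WT region and does not test gain. Mark gene list tests past the threshold ran from 0 (Fisher's exact test, 1 unadjusted with all lists) to 3 (without WT replicate 1).

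H3K27ac similarity within lines exceeded that between lines by 0.0537, 0.0559, 0.063 and 0.0868 on leaving out the DDIT3, FUS-DDIT3, EWS-FLI1 or WT line (exact permutation p = 0.133, 0.133, 0.0667 and 0.0667, and 3 lines cannot give less than 0.0667). Leaving out 1 list gave 0.0428 to 0.122, and for CTCF −0.00179 to 0.0295. For H3K27me3 the Jaccard index over merged regions gave 0.063 (exact permutation p = 0.019) and leaving out 1 list 0.00887 to 0.142.

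In the best-ranked 50% of the lists that called them the gained and lost CTCF regions were 217 and 133 in the DDIT3 line, 129 and 39 in the FUS-DDIT3 line and 3 and 43 in the EWS-FLI1 line. H3K27ac gave 293 and 607, 540 and 135, and 79 and 50 in the same order, and H3K27me3 2300 and 2628, 1139 and 1323, and 951 and 359. At equal list lengths the EWS-FLI1 line gained 2858 and lost 3126 CTCF regions, the FUS-DDIT3 and EWS-FLI1 lines gained 3632 and 1681 H3K27ac regions and lost 3034 and 1686, and they gained 2452 and 4204 H3K27me3 regions and lost 6751 and 3070. With a 50% reciprocal overlap the FUS-DDIT3 line lost 3904 H3K27ac regions, and the EWS-FLI1 line gained 4449, lost 2495 and gained 13692 H3K27me3 regions.

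Leaving out 1 list of the line or WT gave these ranges. For CTCF the DDIT3 line gained 7871 to 23062 and lost 12153 to 21577, the FUS-DDIT3 line gained 10589 to 18090 and lost 9191 to 21512, and the EWS-FLI1 line gained 3988 to 7723 and lost 10984 to 25965. For H3K27ac the DDIT3 line gained 4231 to 12081 and lost 6591 to 19738, the FUS-DDIT3 line gained 8418 to 15576 and lost 3345 to 11297, and the EWS-FLI1 line gained 3639 to 10201 and lost 2125 to 9933. For H3K27me3 the DDIT3 line gained 11382 to 49385 and lost 10674 to 34785, the FUS-DDIT3 line gained 7505 to 53492 and lost 8150 to 36816, and the EWS-FLI1 line gained 8905 to 30630 and lost 4175 to 21931.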

Other observations

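All tests of hypotheses in this part were chosen only after the results were seen.

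Aminoacyl-tRNA synthetase genes were counted as families after some had been named, and not tested against other genes. Of all protein-coding genes 13.6% had a DDIT3 site and 8.58% a FUS-DDIT3 site within 10 kb. Of 20 cytosolic aminoacyl-tRNA synthetase genes, which load tRNAs with amino acids, 10 had a DDIT3 site within 10 kb, among them AARS1, GARS1, IARS1, LARS1, MARS1, NARS1, TARS1 and YARS1, and of 17 mitochondrial ones 4 had, AARS2, LARS2, TARS2 and YARS2. In the FUS-DDIT3 line 10 of 20 cytosolic and 2 of 17 mitochondrial genes had a site, the latter CARS2 and DARS2. Lost CTCF regions lay within 1 kb of a gene end in 17.5%, 24% and 19.9% of cases in the DDIT3, FUS-DDIT3 and EWS-FLI1 lines, and gained ones in 4.47%, 3.62% and 3.54%. For H3K27me3 the lost regions lay there in 9.34%, 4.30% and 3.94% and the gained ones in 1.76%, 2.65% and 2.42%, and these shares were not tested.

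One hypothesis is that sites lie near cytosolic rather than mitochondrial synthetase genes. Over whole families the odds ratio was 3.25 for DDIT3 sites (two-sided Fisher's exact p = 0.173) and 7.5 for FUS-DDIT3 sites (p = 0.0173), but AARS1, IARS1, SARS1 and WARS1 had been named before the families were drawn up. Without them 6 of 16 cytosolic genes had a DDIT3 site and 6 of 16 a FUS-DDIT3 site, with odds ratios of 1.95 (Fisher's exact p = 0.465) and 4.5 (p = 0.118), so the families may or may not differ and these data leave it open.

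Another hypothesis is that H3K27ac gave way to H3K27me3 within a line. Lost H3K27ac regions overlapped gained H3K27me3 of the same line more often than kept ones, with odds ratios of 22.2 in the DDIT3 line (56 of 5971 against 15 of 35117), 6.64 in the FUS-DDIT3 line (10 of 2256 against 26 of 38782) and 10.6 in the EWS-FLI1 line (4 of 1516 against 10 of 39977). Between different lines the odds ratios ran from 0.659 to 4.69, in pairs that share the WT lists as the matched ones do. The value of the DDIT3 line (95% interval 12.5 to 39.2) exceeded each of these, with a lowest 95% limit of the ratio of 1.28. Without H3K27ac replicate 1 of the line it was 28.8, with a lowest limit of 1.62, but without replicate 2 it was 11.9, with a lowest limit of 0.658. For the FUS-DDIT3 line (3.20 to 13.8) and the EWS-FLI1 line (3.31 to 33.8) the lowest limits were 0.358 and 0.441 with all lists. Without replicate 1 or 2 of the line the odds ratio was 4.06 or 4.34 for FUS-DDIT3, below 4.69, and 7.42 or 8.81 for EWS-FLI1. The counts are small, so an exchange cannot be told apart from the effect of shared controls in any of the lines. The intervals treat regions as independent and leave out the spread between replicates.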
